A study of Homo sapiens with 20 samples.

How the data were processed

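Monocytes were isolated from peripheral blood mononuclear cells by magnetic positive selection for CD14, per the labels, from 5 healthy donors and 5 patients with lupus. Per the labels' protocols, total RNA was extracted with 1 of 2 kits depending on the number of cells recovered, and labelled with biotin by a two-cycle amplification, which adds 3' bias. The kit used for each sample is not given in the sources used here, so it was not tested. The deposited values are linear intensity per probe set for 2 chips, U133A with 22283 and U133B with 22645 probe sets. The software that made them is not given in the sources used here; from the values, the mean of the middle 96% of probe sets was 500 on every array, so the deposited intensity had been scaled per array to that target. Array medians ranged from 92.9 to 132.3 on U133A and from 151.6 to 221.8 on U133B. The arrays carry no detection calls used here, and the number of arrays limits the precision. All 20 arrays had a group in the labels, and each person gave 1 array per chip. No pair of arrays held identical values; pairwise correlations of log2 values ran from 0.83 to 0.958 on U133A and from 0.767 to 0.901 on U133B. The labels describe separate donors, so p-values of single genes and of permutation tests reflect the spread between people.

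Choices in this paragraph were made before the data were examined. Control probe sets (68 per chip) and probe sets of XIST, TSIX or Y-linked genes (52 and 32) were left out. Because array medians differed by more than 1.25-fold, each chip was quantile normalised. Values were transformed as log2(signal + c), with c the 10th percentile of the table, 9.44 on U133A and 26.5 on U133B. Probe sets above the array median on at least 5 of 10 arrays were tested, 11179 and 11312. The chips were fitted separately with limma 3.58.1 in R 4.3.3, with lmFit and eBayes using the intensity trend, and p-values were adjusted by Benjamini-Hochberg at 5%. Gene symbols came from the platform annotation, updated through Entrez identifiers to a RefSeq table of GRCh38.p14. On U133A 19034 probe sets had 1 symbol, 1022 several and 2107 none, and on U133B 15405, 543 and 6597; no gene was named from a probe set with several. Some genes of the lists are not analysed here. A gene was read from its brightest kept probe set, on U133A where it had one and otherwise on U133B, except that the largest changes on U133B are given from that chip; no gene had called probe sets in opposite directions (69 and 18 genes had 2 or more called). Fold signs were checked against group means. No coordinates are given, since the probe sets come without a genome build.

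The genes named are, by a rule set beforehand, those past the threshold with no overlap between the groups, namely the 12 largest increases and 8 largest decreases on U133A and 6 and 4 on U133B, up to 4 genes with the largest absolute change per list, and 6 further genes: CD14, CCR7, IRF7, CIITA, TNFSF13B and TLR7. Other genes are said to have been named after their values were seen. The 28 gene lists, fixed beforehand, cover interferon responses, antigen presentation, monocyte subsets, stress and metabolism, and markers of cells that CD14 selection could carry over. They were tested with camera at a preset correlation of 0.01, with an estimated one as the alternative, and adjusted over 43 list-by-chip tests of lists with at least 5 kept genes. The preset value treats the genes of a list as nearly independent, so its p-values do not measure the spread between people alone. The estimated correlation was 0.364 for the interferon-stimulated and 0.262 for the ribosomal list on U133A. List means per array and array quality were compared by exact two-sided permutation tests over 252 splits, adjusted over 16 and 8 tests.

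The test was checked on simulated arrays with the real means and residual spread, with 200 probe sets changed among 11179 on U133A and 11312 on U133B, 50 for each of 4 sizes. For the lupus against healthy comparison, log2 changes of 2 and -2 were recovered in 90% and 74% on U133A and 68% and 68% on U133B. Changes of 1 and -1 were recovered in 54% and 56% on U133A and 22% and 12% on U133B. Of the simulated calls, 4.2% and 2.3% were false. Alternatives tried were other offsets, filters, normalisations, variance models, array weights (statmod 1.5.0 for the robust fit), the GAPDH 3' to 5' ratio as a covariate, stricter thresholds and leaving out each person; leaving out the array with the strongest 3' bias in each group was added after the data were seen. Slide and scan date were not used here. Signals are relative, so group differences in total RNA per cell are not measured.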

Results

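Gene expression was measured in CD14-positive monocytes, a class of circulating phagocytes, from the blood of 5 healthy controls and 5 pediatric patients with newly diagnosed, active systemic lupus erythematosus who had not been treated. Lupus is an autoimmune disease in which type I interferon activity is often raised. Each person's RNA was hybridised to 2 Affymetrix chips, U133A and U133B, giving 20 arrays, 5 per group and chip. The arrays have no read depth, and their precision is limited by 5 people per group. The comparison asks which transcripts differed between lupus and healthy monocytes in patients whose profiles drugs had not altered. Log2 changes are lupus minus healthy on the log2(normalised signal + offset) scale, which understates changes of dim probe sets, and are given with their standard error (SE).

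Lupus monocytes carried much more RNA of genes that interferon switches on. Other rises included the chemokine CCL2 and the complement gene C1QB, and the genes that fell included PID1, ADGRE3 and CD1C. On U133A, 398 of 11179 tested probe sets were higher and 331 were lower in lupus at a false discovery rate of 5%, and 260 and 135 of these differed by at least 2-fold. In terms of named genes, 270 of 6858 rose and 165 fell. U133B, which holds less well characterised transcripts, gave 132 higher and 80 lower among 11312 probe sets, with 85 genes rising and 37 falling among 5852. The 5 lupus and 5 healthy arrays did not overlap for 7.71% of U133A and 4.45% of U133B probe sets, against 0.794% by chance. The first principal component, with 34.6% of the variance, separated the groups on U133A, while on U133B, with 24.1%, the groups overlapped on it. The U133A calls were 54.6% higher ones, and 49.9% (370 higher, 371 lower) when arrays were centred on their median. The U133B calls were 62.3% higher ones, and 80.6% when arrays were centred on their median instead of quantile normalised. The counts moved by more than 1.5 times when some people were left out. On U133A the higher calls were 248 without healthy replicate 5 and 225 without lupus replicate 1, and the lower calls were 186, 201, 161 and 142 without healthy replicates 1, 2, 3 and 5 and 164 without lupus replicate 1. On U133B the higher calls were 87 and 83 without healthy replicates 2 and 5 and 58, 79 and 85 without lupus replicates 1, 2 and 3, and the lower calls were 38, 36, 29 and 30 without healthy replicates 1, 2, 3 and 5 and 27 and 42 without lupus replicates 1 and 2. Without the array with the strongest 3' bias in each group, a choice made after seeing the data, 207 higher and 117 lower calls were left on U133A and 61 and 20 on U133B.

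**Figure D1:**
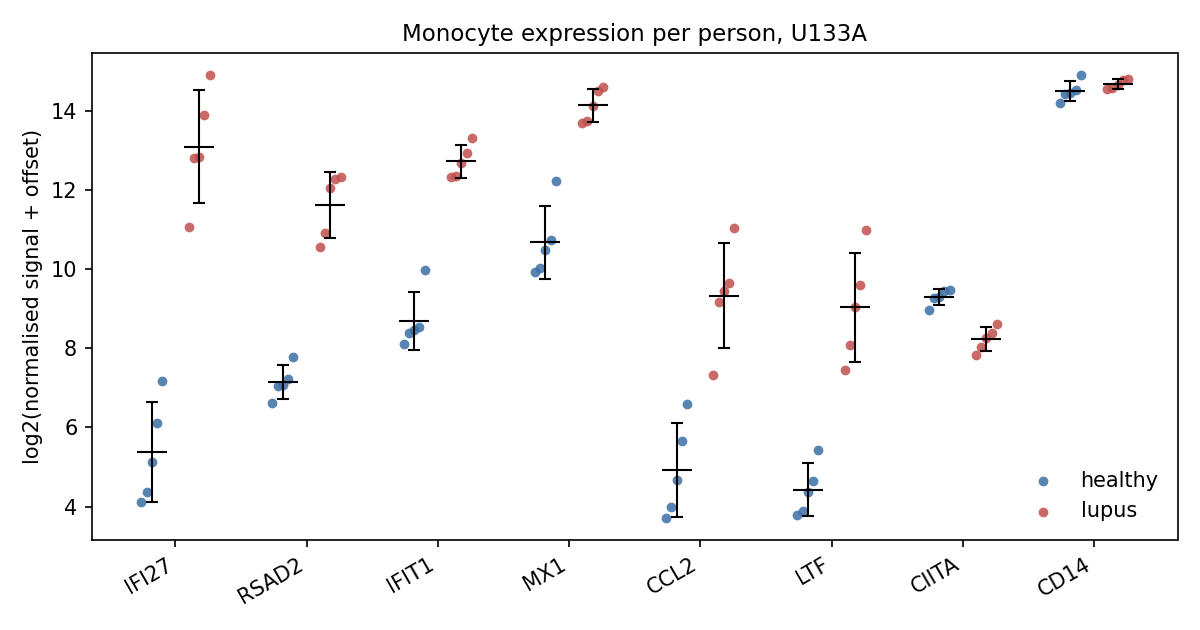
Log2(normalised signal + offset) of 8 genes on U133A, with 1 point per person (5 healthy in blue, 5 lupus in red); black lines are the mean and whiskers the SD. The groups do not overlap for IFI27, RSAD2, IFIT1, MX1, CCL2, LTF and CIITA, whereas CD14 differed by 0.17 with an adjusted p of 0.461.

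Interferon-stimulated genes rose almost as a block. Of 61 measured members of the list, 57 rose and none fell over all probe sets tested, and 60 rose when adjusted over the list alone; all 61 had a positive change. IFI27 showed the largest increase, from a signal of 47.9 ± 52.9 (SD, n = 5) in healthy monocytes to 12440 ± 11100 (SD, n = 5) in lupus, a log2 change of 7.72 ± 0.67 (adjusted p = 2.08e-05). RSAD2, the antiviral enzyme viperin, rose by 4.47 ± 0.35 log2, and the ubiquitin-like modifier protease USP18 by 4.38 ± 0.46. IFITM1, a membrane protein that limits virus entry, rose by 4.19 ± 0.4 and the RNA-binding IFIT1 by 4.03 ± 0.32. MX1, a dynamin-like GTPase that blocks viruses, went from 1975 ± 1600 to 18570 ± 5350 (SD, n = 5), and IFI44L from 998.5 ± 645 to 12400 ± 3300. SIGLEC1, a sialic acid receptor of macrophages, rose by 3.64 ± 0.35, LGALS3BP by 3.67 ± 0.35 and LY6E by 3.45 ± 0.33. IFIT3 rose by 2.91 ± 0.25 on U133A and 3.84 ± 0.31 on U133B, and IFIT2 by 2.51 ± 0.32 and 3.44 ± 0.35. On U133B, EPSTI1 rose by 3.11 ± 0.29 and SAMD9L by 3.04 ± 0.23. The 4 members not called were IRF9 (0.94, adjusted p = 0.0886), TRIM5, CCRL2 and SP100, the last 3 named after their values were seen. The list median was 2.24 on U133A, and camera, which sets a list against all other genes, gave an adjusted p of 2.82e-67 with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.0206 on both U133A and U133B. The list mean per array was 9.12 ± 0.3 in healthy and 11.59 ± 0.37 in lupus (SD, n = 5), higher in all 5 lupus arrays than in any healthy one (exact permutation p = 0.00794, the smallest 252 splits allow, adjusted p = 0.0318).

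Some genes downstream of or feeding into interferon signalling also rose. Of 35 measured nucleic acid sensing genes, 9 rose and 1 fell (13 and 2 adjusted over the list alone). The RNA sensors IFIH1 (2.05 ± 0.26) and RIGI (1.99 ± 0.33), their relative DHX58 (2.59 ± 0.52) and the Z-form nucleic acid sensor ZBP1 (2.16 ± 0.34) rose, and so did IRF7, the transcription factor that drives interferon genes (1.74 ± 0.26, adjusted p = 0.00167); all 5 also stand in the interferon-stimulated list. TLR7 was 0.73 ± 0.29 higher with an adjusted p of 0.153. The sensing list had an adjusted p of 3.82e-05 on U133A with the preset and of 0.0597 with an estimated correlation, and of 0.103 on U133B. Of 22 measured interferon receptor and JAK-STAT genes, 6 rose and none fell (8 and 0 adjusted over the list alone), among them JAK2, a kinase of cytokine receptors (1.1 ± 0.23), whose call ended without the array with the strongest 3' bias in each group, and the transcription factor STAT4 (1.58 ± 0.38), whose call ended without the filter on dim probe sets; this list's adjusted p of 0.0213 on U133A became 0.11 with an estimated correlation, and it was 0.42 on U133B. Of 34 genes that lean towards interferon gamma, 17 rose and 1 fell (23 and 1 adjusted over the list alone). The chemokine CXCL10 rose by 2.9 ± 0.5, APOL6 by 2.96 ± 0.39 and, on U133B, ANKRD22 by 3.04 ± 0.52, while CIITA fell by 1.05 ± 0.19 log2. This list had an adjusted p of 3.07e-09 on U133A and 6.71e-11 on U133B, and 0.166 and 0.0634 as adjusted p with an estimated correlation. TNFSF13B, the B cell survival factor BAFF, was already bright in healthy monocytes (28540 ± 5760, SD, n = 5, U133B) and was 0.5 ± 0.16 higher in lupus with an adjusted p of 0.137.

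**Figure D2:**
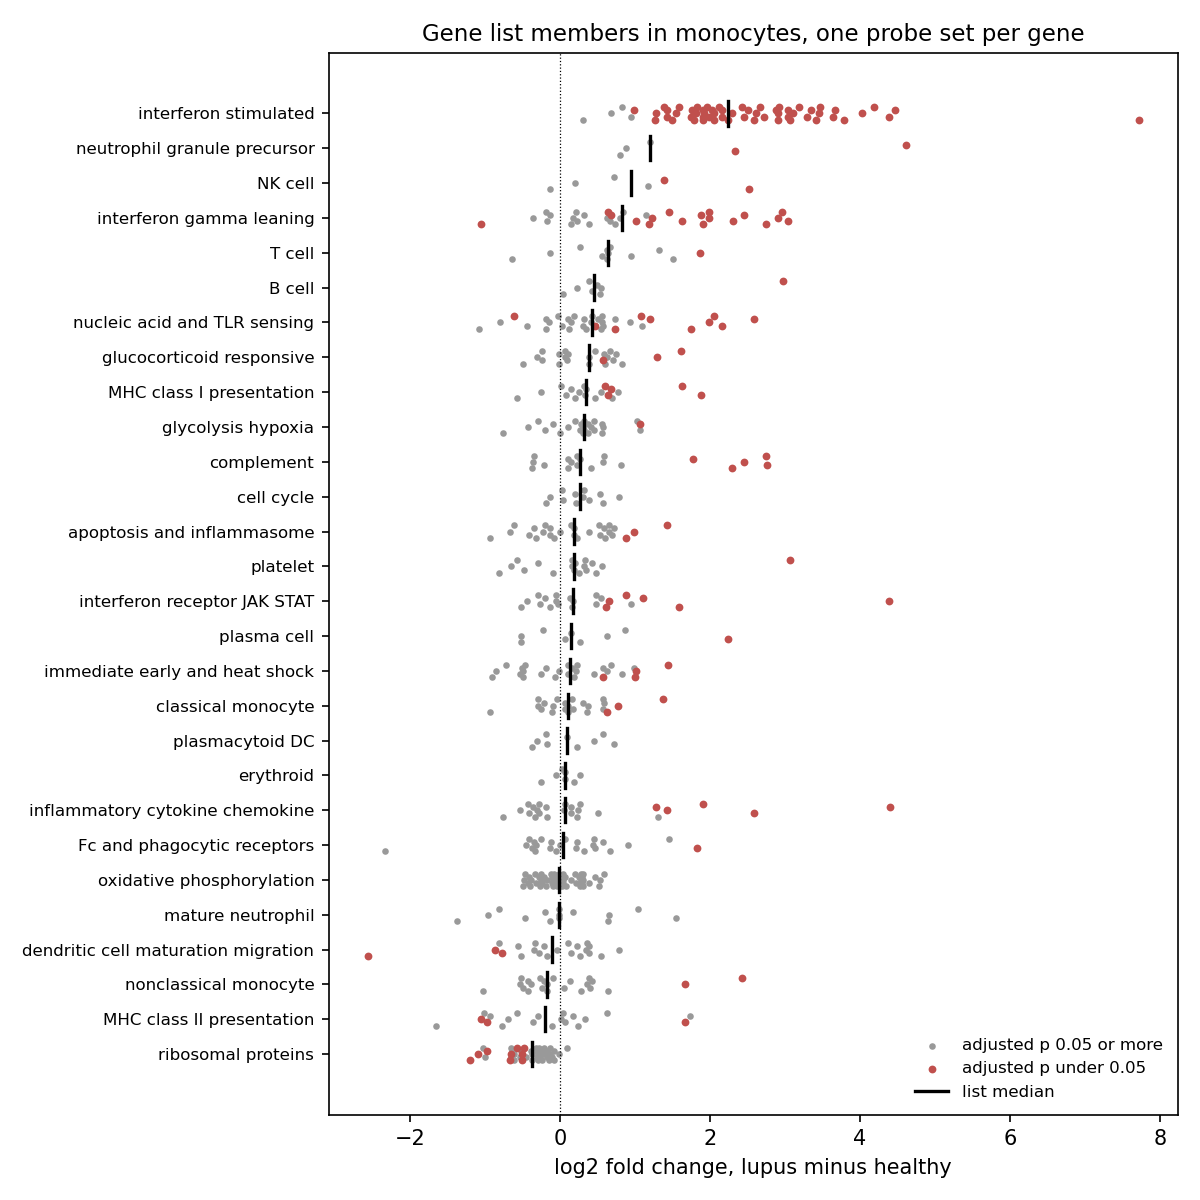
Log2 change, lupus minus healthy, of each measured member of the 28 gene lists (1 probe set per gene, U133A where kept and otherwise U133B); red points passed an adjusted p of 0.05, grey points did not, and the bar is the list median. Interferon-stimulated genes lie to the right (median 2.24) and ribosomal protein genes to the left (median -0.371).

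Few antigen presentation genes passed the test, and the difference between the class I and class II pathways was not tested. Of 19 MHC class I pathway genes, 5 rose and none fell (7 and 0 adjusted over the list alone): the peptide transporter TAP1 (1.88 ± 0.23), the immunoproteasome subunit PSMB9 (1.63 ± 0.19), and, named after their values were seen, PSMB8, TAPBP and HLA-E. The other 14 were not called. Its adjusted p was 5.55e-05 on U133A, and 0.134 with an estimated correlation, and 0.904 over 6 genes on U133B. Of 20 class II pathway genes, 1 rose and 2 fell (1 and 4 adjusted over the list alone). CIITA, the master activator of class II transcription, fell from 619.9 ± 83.9 to 296.6 ± 63.5 (SD, n = 5; adjusted p = 0.00542), the peptide loading gene HLA-DMB fell by 0.98 log2 (adjusted p = 0.0185, named after its value was seen), and the lysosomal protease CTSL rose by 1.66 ± 0.27. HLA-DQA1 had a log2 change of -1.66 ± 1.32 with an adjusted p of 0.486; HLA genes are polymorphic, so their probe sets can measure alleles unequally and such values are uncertain. The class II list had a median of -0.203 on U133A (adjusted p = 0.405) and of -0.431 over 6 genes on U133B (adjusted p = 0.0448, and 0.166 as adjusted p with an estimated correlation). The U133B call held in 3 of the 10 fits without 1 person, with an adjusted p of up to 0.123.

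Genes of dendritic cell maturation and migration gave no rise: of 22 measured, none rose and 3 fell, also when adjusted over the list alone. CD1C, which presents lipids and marks a dendritic cell class, fell from 1240 ± 390 to 260.6 ± 183 (SD, n = 5; log2 change -2.57 ± 0.53, adjusted p = 0.0121), CD83 by 0.87 ± 0.23 and CD1D, named after its value was seen, by 0.77 ± 0.16. The CD1C call ended without the array with the strongest 3' bias in each group, and CD83 passed the test in 1 of the 10 fits without 1 person (adjusted p up to 0.0996). The chemokine receptor CCR7 had a log2 change of 0.79 ± 0.52 (adjusted p = 0.388). The list median on U133A was -0.191 (adjusted p = 0.144). The selection marker CD14 itself was bright in both groups, at 23470 ± 4330 and 26150 ± 2190 (SD, n = 5), with a log2 change of 0.17 ± 0.13 (adjusted p = 0.461) that became -0.27 with the deposited scaling or with median centring.

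Monocyte subset genes changed little as groups. Of 23 classical monocyte genes 3 rose and none fell (5 and 0 adjusted over the list alone), namely the chemokine receptors CCR1 (1.37 ± 0.27) and CCR2 (0.77 ± 0.15) and PLBD1 (0.62 ± 0.15). The CCR1 call ended without the array with the strongest 3' bias in each group. PLBD1 was called in 7 of the 10 fits without 1 person (adjusted p up to 0.0604), and its call ended with the deposited scaling and with median centring. That list's median was 0.098 on U133A (adjusted p = 0.0435), its adjusted p was 0.445 with an estimated correlation, the median became -0.055 with the deposited scaling, and the call ended without healthy replicate 2 or 3 or lupus replicate 4 or 5 (adjusted p up to 0.166). Of 23 nonclassical monocyte genes 2 rose and none fell (2 and 0 adjusted over the list alone), IFITM2, which is also interferon-stimulated, by 2.43 ± 0.21 and CTSL by 1.66 ± 0.27. IFITM2 was read by a probe set of the type that can cross-hybridise, for example with its relatives IFITM1 and IFITM3, and is uncertain. The list's median of -0.103 and mean of 0.151 on U133A differ in sign, with an adjusted p of 0.42. Of 24 Fc and phagocytic receptor genes, AXL, a receptor for dying cells, rose by 1.83 ± 0.46 and none fell (1 and 1 adjusted over the list alone). AXL was called in 2 of the 5 fits without 1 person that kept it (adjusted p up to 0.0766), and its call ended without the filter on dim probe sets. FCER1A, a chain of the high-affinity IgE receptor, had a log2 change of -2.34 ± 0.66 with an adjusted p of 0.0513.

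A few chemokine and complement genes were among the larger increases. Of 25 inflammatory cytokine and chemokine genes, 5 rose and none fell (6 and 0 adjusted over the list alone). CCL2, which attracts monocytes, went from 30.7 ± 34.6 to 855.1 ± 726 (SD, n = 5), a log2 change of 4.4 ± 0.64 (adjusted p = 0.00126). TNFAIP6 rose by 2.58 ± 0.53, CCL4 by 1.9 ± 0.41 and the interleukin 1 receptor antagonist IL1RN by 1.43 ± 0.22, as did CXCL2, named after its value was seen and read by a probe set that can cross-hybridise. The list as a whole had a median of 0.056 (adjusted p = 0.386). Of 19 complement genes, 5 rose and none fell (7 and 0 adjusted over the list alone): all 3 chains of the first component C1q, C1QA (2.29 ± 0.52), C1QB (2.75 ± 0.5) and, on U133B, C1QC (2.76 ± 0.47), together with its inhibitor SERPING1 (2.45 ± 0.47), which is also in the interferon-stimulated list, and C2, named after its value was seen. The C1QA call ended without healthy replicate 5 or lupus replicate 1 (adjusted p up to 0.0519) and without the array with the strongest 3' bias in each group. The complement list had an adjusted p of 0.0336 on U133A, and of 0.134 with an estimated correlation, and the call ended without healthy replicate 5 or lupus replicate 4 or 5 (adjusted p up to 0.0769) and with the deposited scaling (adjusted p = 0.081). With the filter at the 75th percentile the direction given by camera reversed (10 genes, adjusted p = 0.941).

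Of 28 apoptosis and inflammasome genes, 3 rose and none fell (5 and 3 adjusted over the list alone): the death ligand TNFSF10 (1.43 ± 0.23), which is also interferon-stimulated, the death receptor FAS (0.98 ± 0.22), and CASP10 (0.88 ± 0.24). FAS was called in 9 of the 10 fits without 1 person and CASP10 in 2, and both calls ended without the array with the strongest 3' bias in each group. Of the 4 other FAS probe sets 3 had the same sign and 1 was called. Of 28 immediate early and heat shock genes, JUN (1.44 ± 0.39), FOS (1.01 ± 0.27), MYC (1 ± 0.26) and DUSP1 rose and none fell (5 and 1 adjusted over the list alone); JUN was read by a probe set that can cross-hybridise, and the JUN, FOS and MYC calls held in 1, 3 and 4 of those 10 fits. All 3 calls ended without the filter on dim probe sets and without the arrays of strongest 3' bias, and those of FOS and MYC also with the deposited scaling and with median centring. Neither list passed the test on U133A, with adjusted p of 0.405 and 0.42. Of 23 glucocorticoid-responsive genes, the metallothioneins MT1X (1.61 ± 0.36) and MT2A (1.29 ± 0.28), which bind metals, and DUSP1 rose and none fell (5 and 0 adjusted over the list alone); MT1X and MT2A were read by probe sets that can cross-hybridise with their relatives, and DUSP1 was named after its value was seen. That list's adjusted p was 0.0378 on U133A, and 0.32 with an estimated correlation, and 0.717 on U133B, and its call ended without healthy replicate 1 or lupus replicate 4 or 5 (adjusted p up to 0.139). Of 25 glycolysis and hypoxia genes, PFKP, a phosphofructokinase, rose by 1.07 ± 0.2 and none fell (1 and 0 adjusted over the list alone). The list median was 0.302 on U133A (adjusted p = 0.0226, and 0.543 as adjusted p with an estimated correlation; 0.42 on U133B), and the call ended without healthy replicate 3 or lupus replicate 1 or 4 (adjusted p up to 0.0938). With the deposited scaling, the glucocorticoid and glycolysis lists had adjusted p of 0.0905 and 0.118.

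Some genes of the protein synthesis machinery fell in lupus. Of 43 ribosomal protein and translation elongation genes, 9 fell and none rose (19 and 0 adjusted over the list alone), and 42 had a negative change. RPL10A fell by 1.2 ± 0.25 log2, from 8553 ± 2530 to 3793 ± 1360 (SD, n = 5), and RPL18 by 1.09 ± 0.26, a call that held in 5 of the 10 fits without 1 person and ended without the array with the strongest 3' bias in each group. The list median was -0.371 on U133A and became -0.732 with the deposited scaling. Camera gave an adjusted p of 7.47e-11 on U133A, lost with an estimated correlation (adjusted p = 0.166), and of 6.71e-11 on U133B, kept with an estimated correlation (adjusted p = 0.0206). Ribosomal protein probe sets can cross-hybridise with pseudogenes and relatives, and some of those on U133B are among the 100 probe sets that both chips carry. In the same arrays the T, NK and B cell list means were 0.69, 1.13 and 0.74 log2 higher in lupus, with exact permutation adjusted p of 0.0725, 0.0725 and 0.0318. Camera gave these lists adjusted p of 0.37, 0.344 and 0.37 with an estimated correlation. Oxidative phosphorylation genes showed no called change among 53 (0 rose and 0 fell, also when adjusted over the list alone). Of these 53, 9 had an unadjusted limma p under 0.05. Camera gave that list an adjusted p of 0.83 (median -0.015), and on U133B its median and test differ in sign. None of 12 cell cycle genes was called (0 and 0 adjusted over the list alone, and 0 with an unadjusted limma p under 0.05). The cell cycle list had a median of 0.306 on U133A (camera adjusted p = 0.312). Without the filter on dim probe sets the cell cycle list passed the test as higher.

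The decreases given here are the largest among genes past the threshold whose lupus and healthy arrays did not overlap, each read from its brightest kept probe set on that chip. PID1, a regulator of insulin receptor signalling, fell from 1918 ± 332 to 265.4 ± 247 (SD, n = 5; log2 change -3.33 ± 0.51, adjusted p = 0.00177). ADGRE3, an adhesion G protein-coupled receptor of myeloid cells, fell from 483 ± 122 to 64.1 ± 47 (log2 change -2.9 ± 0.34, adjusted p = 0.000245). The protease ADAMTS5 fell by 2.63 ± 0.52, OLFM1 by 2.43 ± 0.42 (its 1 other probe set was not called) and the calcium channel subunit CACNA2D3 by 2.32 ± 0.43. EVX1 and GNRH2 fell by 1.43 ± 0.34 and 1.46 ± 0.36, both read by probe sets of the type that can cross-hybridise and therefore uncertain; EVX1 was called in 6 of the 10 fits without 1 person, and GNRH2 in 4 of the 5 that kept it. On U133B, RASSF3 fell by 1.55 ± 0.27 (its 1 other probe set was not called), GGTA1 by 1.55 ± 0.28 and OLIG1 by 1.54 ± 0.37 (called in 3 of the 10 fits without 1 person), and a TFRC probe set of the cross-hybridising type by 1.94 ± 0.38, a call lost without healthy replicate 3 (adjusted p = 0.06). The 2 other TFRC probe sets, both on U133A, were not called, and 1 of them had the opposite sign, so a decrease of TFRC itself is uncertain. KLHDC7B on U133B rose by 3.02 ± 0.35.

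Some markers of other blood cells differed between the groups. Among neutrophil granule genes, which are made in marrow precursors, LTF, lactoferrin, went from 14.1 ± 12 to 749.2 ± 755 (SD, n = 5; log2 change 4.61 ± 0.57) and the defensin DEFA4 from 68.3 ± 28.1 to 432.7 ± 260 (2.33 ± 0.43). These were the 2 called of 5 measured, with none falling (4 and 0 adjusted over the list alone), and the list mean was 1.97 log2 higher in lupus (exact permutation p = 0.00794, adjusted p = 0.0318). Its camera adjusted p of 0.000368 became 0.166 with an estimated correlation. Of 14 mature neutrophil genes none was called (2 rose and 3 fell adjusted over the list alone, and 6 had an unadjusted limma p under 0.05), with a U133A median of -0.018 against a mean of 0.079. Among lymphocyte lists, 1 of 12 T cell genes rose (LCK, 1.86 ± 0.47, called in 4 of the 10 fits without 1 person), 2 of 6 NK cell genes (NKG7, 2.52 ± 0.58, called in 7 of those 10, and GZMA, 1.38 ± 0.31) and 1 of 8 B cell genes (STAP1, 2.97 ± 0.49); none fell, and adjusted over the list alone 3, 3 and 1 rose. The list means were 0.69, 1.13 and 0.74 log2 higher, with exact permutation p of 0.0317, 0.0238 and 0.00794 and adjusted p of 0.0725, 0.0725 and 0.0318. The B cell groups nearly met, with a highest healthy mean of 7.14 and a lowest lupus mean of 7.16. STAP1 had the largest change of the B cell list, whose median change on U133A was 0.494. Camera gave the T and NK lists adjusted p of 0.0226 and 0.0213, and 0.37 and 0.344 as adjusted p with an estimated correlation; the B cell list had 0.0515, and 0.37 with an estimated correlation. The T cell call ended without healthy replicate 1 or 4 or lupus replicate 5 (adjusted p up to 0.0772), and with the deposited scaling (adjusted p = 0.058). CD38 was the called one of 9 plasma cell genes (2.24 ± 0.38; 2 and 0 adjusted over the list alone), and CLU the called one of 18 platelet genes (3.07 ± 0.66; 1 and 0 adjusted over the list alone), a call that ended without the array with the strongest 3' bias in each group. No gene of the plasmacytoid dendritic cell list (9 genes) or the erythroid list (7 genes) was called, also when adjusted over the list alone, and 0 had an unadjusted limma p under 0.05. The plasma cell, plasmacytoid, platelet and erythroid list means on U133A differed by 0.39, 0.17, 0.27 and 0.04 log2, with adjusted p of 0.0725, 0.68, 0.68 and 0.873.

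**Figure D3:**
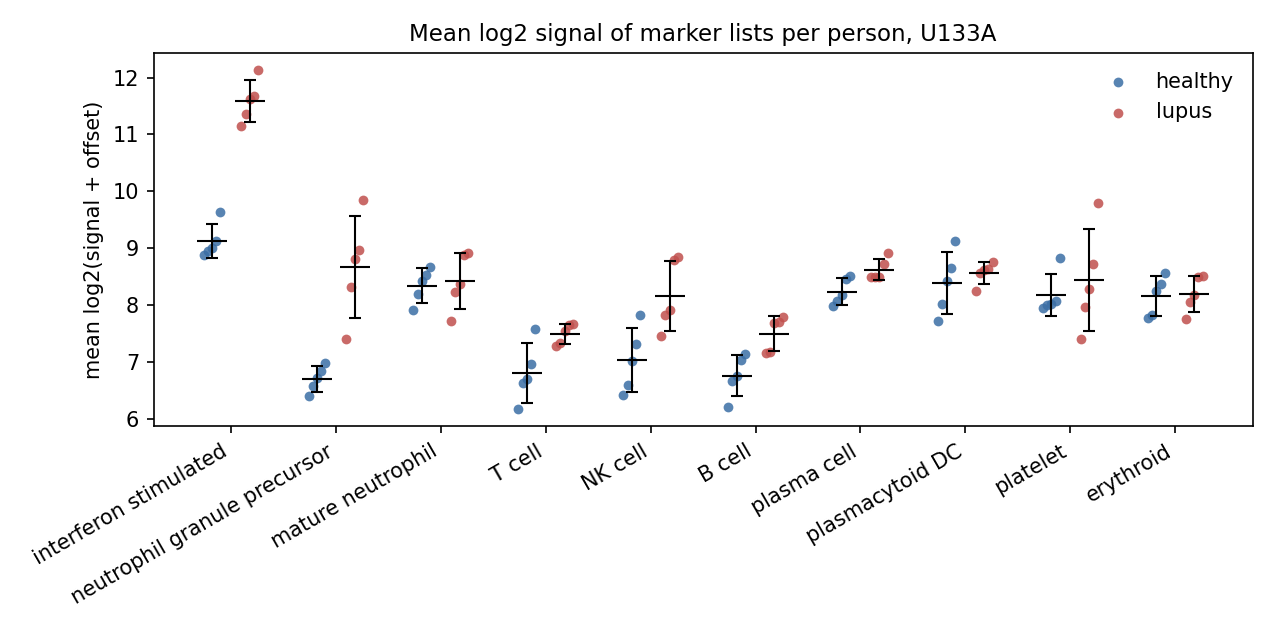
Mean log2(normalised signal + offset) over the kept genes of 10 lists on U133A, with 1 point per person (5 healthy in blue, 5 lupus in red); black lines are the mean and whiskers the SD. The interferon-stimulated, granule precursor and B cell lists show no overlap of the groups, and mature neutrophil means were 8.34 and 8.42. The B cell groups nearly met, at 7.14 in the highest healthy and 7.16 in the lowest lupus array.

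The groups did not differ detectably in RNA integrity as the arrays measure it. The log2 ratio of the 3' to the 5' control probe set of GAPDH was 1.29 ± 0.656 in healthy and 1.09 ± 0.447 in lupus on U133A (SD, n = 5; exact permutation p = 0.603), and that of ACTB was 3.35 ± 0.504 and 3.29 ± 0.389 (exact permutation p = 0.865). The array median was 116 ± 9.67 in healthy and 104 ± 8.01 in lupus before normalisation (SD, n = 5; exact permutation p = 0.0635). For 1929 genes kept on both chips, the log2 changes had a Pearson correlation across genes of 0.409 and a Spearman correlation of 0.283, and 60.1% had the same sign; genes are not independent replicates. Of these genes, 123 were called on U133A, and 98 of the 123 had the same sign on U133B. All 23 genes called on both chips moved the same way. No other kept probe set was called for APOL6, MT1X, TNFSF10, CCR1, CCR2 and PFKP, though all had the same sign. Of the 2 other RIGI probe sets, 1 had the same sign and was called. For the 100 probe sets present on both chips the correlation was 0.959. Further calls of named genes that ended without the arrays of strongest 3' bias were those of CD83, EVX1, LCK, OLIG1 and PLBD1, and these 5 and CASP10 also ended without the filter on dim probe sets. The CD83 and OLIG1 calls ended with the deposited scaling and with median centring as well. In all, 16 named gene calls ended without the arrays of strongest 3' bias, a setting that also has fewer people. With the GAPDH ratio as a covariate 2 ended, those of CASP10 and FOS.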

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

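The test of lower lymphocyte content for the ribosomal pattern was chosen after its result had been seen; the other tests of this part were chosen before. In groups of 5 arrays, 18 of 316 tested had 1 array far from the other 4, where chance gives about 1 in 20, or 16. The value is the gap of the outermost array to its neighbour divided by the group's range, against a critical value of 0.71. On U133A, 1 of the 5 healthy arrays lay far above the others for IFIT1 (0.764), CD5 (0.732), GNRH2 (0.819) and the platelet list mean (0.859). In other cases 1 of the 5 healthy arrays, which need not be the same one, lay far below the others for DHX58 (0.845), CD38 (0.756), BPGM (0.743), ALDH1A1 (0.831), HLA-DQA1 (0.776), PID1 (0.722) and the ACTB 3' to 5' ratio (0.783). Healthy replicate 4 was the outlying array for IFIT1, the platelet list mean and the ACTB ratio. It also had the highest interferon-stimulated list mean of the healthy arrays on U133A (9.64). Of the lupus arrays, 1 of 5 lay above the others for FCGR3B (0.713) and CCR2 (0.719), and below them for COX6A1 (0.743), RPLP2 (0.741) and TNFRSF10C (0.748). On U133B, 1 healthy array was far above the others for EPSTI1 (0.717) and 1 lupus array far below for OLIG1 (0.713). For all 4 counts of called probe sets, only the real split gave as many calls, 1 of 100 splits into 5 and 5. This argued against chance but did not exclude it. The other splits mix lupus and healthy arrays, which widens the spread within each side and can lower their counts. Group differences unrelated to lupus, such as the RNA kit, were not tested this way. The real U133A counts of 398 higher and 331 lower stood against 3 in the highest other split, and the U133B counts of 132 and 80 against 11.

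Of 5 measured granule genes LTF and DEFA4 rose in lupus, and the list had an adjusted p of 0.166 with an estimated correlation. The median change of the 5 kept genes stayed at 0.75 or more whichever lupus array was left out. This does not exclude a single lupus array. The filter kept genes dim in healthy arrays, such as LTF, only where all 5 lupus arrays were above their median. DEFA4 was called in all 10 fits without 1 person. Neutrophil precursors among the selected cells stay open: without the filter on dim probe sets, the other 18 list members had a median change of 1.201, with CEACAM8 at 2.9, OLFM4 at 2.11, ELANE at 2.2 and CAMP at 2.05, although AZU1 was at -0.12 and CHI3L1 at -0.14. These are dim genes, and CD14 selection would remove most such cells, but some may have been carried over. A change within monocytes was not tested and stays open.

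Of 43 ribosomal protein and elongation genes on U133A, 9 fell and 42 had a negative change in lupus, with an adjusted p of 0.166 for the list with an estimated correlation. RNA degradation as the whole cause was argued against: with the GAPDH 3' to 5' ratio as a covariate the list median minus that of all genes was -0.308, against -0.364 without. Scaling with a constant factor per array was argued against, since with the other scalings the difference was -0.7 or lower. Those scalings cannot test a difference between arrays that varies with signal. The size of the fall did depend on scaling, with a list median of -0.371 after quantile normalisation and -0.732 with the deposited scaling. A lower lymphocyte share in lupus was argued against, because the T cell list mean was 0.69 higher in lupus. The RNA extraction kit was not tested and stays open, as does a difference between lupus and healthy monocytes themselves.

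A few lymphocyte markers rose in lupus, 1 of 12 T, 2 of 6 NK and 1 of 8 B cell genes, and the lists had adjusted p of 0.37, 0.344 and 0.37 with an estimated correlation. A single array was argued against for the kept T cell genes, with a list difference of 0.53 or more whichever array was left out. The filter on dim probe sets can favour genes that are high in all lupus arrays, so this covers the kept genes only. Lymphocytes carried over through the CD14 selection stay a candidate explanation: without the filter on dim probe sets the T, NK and B cell lists had median changes of 0.622, 0.381 and 0.448, the lowest being 0.381, with 18 of 22, 13 of 19 and 16 of 18 genes positive. Without that filter 0 T, 3 NK and 1 B cell genes were called. The called markers, NKG7, STAP1, GZMA and LCK, had mean signals of 941.3, 306, 236.6 and 195.3 in lupus. Expression of these genes by lupus monocytes themselves was not tested.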

How the results depend on the processing

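Leaving out the array with the strongest 3' bias in each group was the one alternative chosen after seeing the data. The interferon-stimulated list on U133A kept its direction and call under every alternative run, with medians from 2.013 to 2.422 without 1 person. Counts depended more on the settings. U133A higher calls were 260 with a 2-fold minimum, 154 at a false discovery rate of 1%, 207 without the arrays of strongest 3' bias, and 225 to 424 without 1 person. U133A lower calls were 135, 62, 117 and 142 to 387 in the same order, and 191 without the filter on dim probe sets. U133B higher calls were 52 at 1%, 61 without the arrays of strongest 3' bias, 63 without the intensity trend, and 58 to 152 without 1 person. U133B lower calls were 13, 20, 24 and 27 to 108 in the same order, 44 without the filter, 38 with median centring, 126 with the stricter filter, 127 with array weights and 128 with the GAPDH ratio as covariate. Stricter thresholds can only lower such a count; for the other settings the cause was not tested. The correlation of the chips fell to 0.256 without the filter, which adds dim genes. The complement list on U133A had a median of 0.116 with the stricter filter, where camera's direction reversed (10 genes, adjusted p = 0.941); the cause was not tested. Of 134 named genes, 95 kept their side of the threshold under every alternative run that kept them. So did 53 of the 74 called ones, which also kept their direction. A gene that the filter left out has no value in that run. CCL2, LTF and STAP1, for example, had a value in only 5 of the fits without 1 person. Some genes that were not called, such as CD14 and PPBP, changed direction under an alternative. Of 42 other list results 23 kept their side of the threshold, and so did 2 of the 16 called ones, which also kept their direction. The median of some uncalled lists changed sign, such as oxidative phosphorylation on U133B (0.028, and -0.055 with the deposited scaling). Without the filter on dim probe sets, the cell cycle, plasma cell and B cell lists on U133A and the sensing list on U133B also passed. No named gene with a call reversed. Replicate numbers are only an order within each group. The granule, NK and B cell lists fell under 5 kept genes, and so have no value, in some fits without 1 person, and the first 2 also without the arrays of strongest 3' bias. No paired analysis was possible because no person is in both groups. In simulation over all tested probe sets, 2-fold increases were recovered in 54% on U133A and 22% on U133B; recovery by signal level was not tested.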

Other observations

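The genes and both tests in this part were chosen after values had been seen. Outside the fixed lists, EMP1, an epithelial membrane protein, rose by 2.93 log2 in lupus (adjusted p = 3e-05), and the small heat shock protein HSPB1 by 2.95. The homeobox gene HESX1 rose by 3.19, the GMP reductase GMPR by 3.01, OPTN, an autophagy receptor, by 2.64 and the fatty acid receptor FFAR2 by 2.22. KMO, an enzyme of tryptophan breakdown, rose by 1.78, and BLVRA, biliverdin reductase, by 1.6. On U133B, NEXN rose by 2.71, the ubiquitin ligase RNF213 by 2.87, the RNA exonuclease PNPT1 by 1.92 and the metabolite receptor GPR84 by 1.96.

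Among decreases, the sorting receptor SORL1 fell by 1.37 on U133A and by 1.46 on U133B. RTN1 fell by 2.72 and PALLD by 1.94, with overlap between the groups. CD44, the hyaluronan receptor, fell by 0.87 on its brightest probe set, and IMPDH2, an enzyme of GTP synthesis, by 1.38.

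A first hypothesis was that translation initiation factors moved with the ribosomal protein genes. Of 41 EIF1 to EIF6 genes kept on U133A, 9 fell and 1 rose, and 31 had a negative change. EIF3L fell by 1.41 ± 0.19, EIF3M by 1 ± 0.16 and EIF4B by 0.98 ± 0.19, whereas the interferon-induced kinase gene EIF2AK2 rose by 1.59 ± 0.2. The median was -0.194, short of the -0.2 set for the test, and camera with an estimated correlation gave p = 0.00189. The 41 were picked by symbol and include regulators of the factors, among them EIF2AK2 and EIF4EBP1 (-0.93). The median is therefore not that of initiation factors alone, and a joint decrease of the factors is left open.

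A second hypothesis was that fewer CD1C-positive dendritic cells were among the selected cells in lupus. Without the filter on dim probe sets, 7 other markers of these cells had a median change of -0.359, from -2.34 for FCER1A and -0.82 for CLEC10A to 0.39 for FLT3, and none was called. Monocytes also express some of these markers, such as CLEC10A. The values go both ways, so a lower share of these cells could account for CD1C but cannot be told apart here from lower CD1C expression in monocytes.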
